A study of Mus musculus with 10 samples.

How the data were processed

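RNA sequencing was done on cells that express green fluorescent protein from the Hopx promoter, sorted by flow cytometry from the intestines of mouse embryos at embryonic day 18.5. Hopx is a homeodomain protein used to mark slow-cycling cells of the intestinal crypt. Per the labels, crypts were dissociated mechanically, cells were sorted into Trizol, total RNA was taken and paired reads were sequenced on an Illumina HiSeq. The strain label names C57BL6/J and 129S4. The 10 libraries comprised 5 from p57KO embryos, which lack p57Kip2, and 5 from p57WT embryos. p57Kip2 is the cyclin-dependent kinase inhibitor encoded by the imprinted gene Cdkn1c. The design text speaks of 5 intestines of each genotype, so each library was taken as a separate animal, although no animal identifiers were given. Each library's label also carries a number, 607, 608 or 740, whose meaning was not given in the sources used here. Number 607 covers p57KO 1, p57KO 2 and p57WT 1. Number 608 covers p57KO 3, p57KO 4 and p57KO 5, and number 740 covers p57WT 2 to p57WT 5. Only 607 holds both genotypes, so label number and genotype are nearly confounded.

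The deposited table held whole-number counts of reads per gene for each library, not normalized, per the file headers and the values. It also held a signal value per library, which was the count divided by one size factor per library, as deposited by the authors. The authors' comparison of the genotypes was deposited as log2 fold changes with their standard errors on the log2 scale, a Wald score, and a p-value with its adjusted p-value, per the file headers. The submitters' processing notes name FastQC, Trim Galore, STAR 2.6.1d, Cufflinks 2.2.1, HTSeq 1.0 and DESeq2 1.22.2 with the mouse build mm10, also called GRCm38. The role of each tool, the annotation release and the strand setting were not given in the sources used here. The table listed 20579 genes, and its smallest mean normalized count was 3.00, so genes below about that level were not analysed here. It held no mitochondrially encoded gene, so no mitochondrial share could be computed. Of the identifiers, 20558 matched the GENCODE M21 annotation of GRCm38, which gave the coordinates. Because the strand setting was not given, reads of a gene and of an overlapping antisense gene could not be told apart, and values of Kcnq1ot1, which overlaps Kcnq1, are uncertain. Reads of near-identical copies could also be split or lost, which makes values of Hba-a1, Defa24, Lilrb4a and Stfa1 uncertain.

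Total counts per library ranged from 8037887 to 26809231. At these depths 3 counts, taken as the floor for a gene with no reads, corresponded to between 0.112 and 0.373 CPM (counts scaled to a common library size). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Ratios of pooled counts carry exact 95% intervals for 2 Poisson counts. No pair of libraries of one genotype was alike to within sampling noise: the chi-square per degree of freedom over genes ranged from 10.2 to 339 among p57WT pairs and from 50.1 to 338 among p57KO pairs.

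The genotypes were compared with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test on the counts, scaling by trimmed mean of M values (TMM), the tool's expression filter and genotype as the only term. The filter removed 3869 genes and left 16710. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. All adjusted p-values of single genes come from this edgeR fit unless another is named. Fold changes are log2 values of p57KO over p57WT with a standard error (SE), and CPM values are means ± SD over 5 libraries per genotype. Label numbers were compared within each genotype by edgeR contrasts in a model of the 4 combinations of genotype and number. The lone p57WT library of 607 was then assumed to vary like the other groups.

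Before the data were examined, 30 lists of genes were fixed for intestinal cell types, other cell types that the sort could hold, the cell cycle, imprinting and stress. Of these, 29 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists. Each list was also tested with a correlation estimated from the data and with fry. Over all libraries no list call held with an estimated correlation, which was not run for the alternatives. The rule for named genes was fixed at the same time. It took Cdkn1c, then the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean of at least 5 CPM whose sign held when each library was left out, and up to 4 members of each list with the smallest p, plus any further member that passed. Not every gene that the rule picked is named here. Genes without a proper symbol, Xist and Y-linked genes were left out of the largest changes. Gast, Lgr5, Ascl2, Olfm4, Tff2, Gkn3, Muc6 and Ctrb1 were named after their values were seen.

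Mean marker levels per library are means of log2(CPM + 1) over a list, compared by two-sided exact permutation tests, for which 5 against 5 libraries cannot give a p below 0.00794. Alternatives fixed beforehand were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma voom, other filters, the title number as a block, the label number as a term, subsets by label number, removal of erythroid genes, 1 surrogate variable from sva 3.50.0, a 2-fold minimum and leaving out each library. Others were added after the data were seen. These were a term or subset for the share of counts on 3 ribosomal RNA repeat features (Gm15564, Gm23935 and Mir6236, above or below 1%), removal of those features, scaling to the epithelial markers, the smooth muscle mean as a covariate, and leaving out p57KO 1 and p57KO 2 together. Smooth muscle means did not overlap between genotypes, so that covariate could not be separated from genotype. Changes under it do not show muscle share as a cause. The expression filter was run again for each subset of libraries. Leaving out 1 library thus left 16959 to 17298 genes, and the tested members of a list could differ.

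The steps were tested on simulated counts for 16710 genes, or 20276 for comparisons of label numbers, of which 100 were changed 2-fold and 100 were changed 4-fold. For 5 against 5 libraries edgeR recovered 5% of the 2-fold and 67% of the 4-fold changes, with 2 false calls among 74. Few genes were changed there, while 36.5% of genes were called in the data, where the cutoff on p was thus looser. These rates therefore do not give the power reached in the data. DESeq2 recovered 26% and 83%, with 23 false calls among 132, and voom recovered 4% and 65%. For 608 against 607 within p57KO, edgeR recovered 0% and 20%, and for 740 against 607 within p57WT 0% and 1%. For the genotypes within 607 it recovered 0% of either size. In the list test the 1 list that had been shifted was called, with 0 others. Genes were simulated independently, while the correlation estimated from the data was, for example, 0.53 for the enteroendocrine list. The list test was therefore not checked for members that move together.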

Results

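Counts per gene were available for 10 libraries of sorted Hopx-GFP cells from the intestine of late mouse embryos, 5 from p57KO and 5 from p57WT embryos. Total counts were 11711638, 25043153, 26809231, 25463840 and 10684179 in p57KO 1 to 5, and 8660311, 25527896, 8382752, 8037887 and 9020153 in p57WT 1 to 5. The deeper libraries were therefore mostly p57KO. The share of counts on 3 ribosomal RNA repeat features differed by library. It was 0.435%, 0.0651%, 0.0592% and 0.0655% in p57KO 1 to 4, 9.47% in p57KO 5, 0.0301% in p57WT 2, and 15%, 14.9%, 17.0% and 16.9% in p57WT 1, 3, 4 and 5. Low shares thus fell on 4 p57KO libraries and 1 p57WT library. The first principal component of the log2 CPM values held 54.2% of the variance and separated all p57KO from all p57WT libraries.

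The comparison asks how the transcriptome of Hopx-expressing intestinal cells differs without p57Kip2. Cdkn1c, the gene of p57Kip2, was examined first because it checks the genotype labels. Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050, minus strand, GRCm38) was nearly absent from every p57KO library. Its level was 2.06, 0.25, 0.77, 0.15 and 0.96 CPM in p57KO 1 to 5 and 164, 151, 198, 181 and 458 CPM in p57WT 1 to 5. The means were 0.840 ± 0.764 and 230 ± 129 CPM (SD, n = 5 each), and the log2 fold change was -8.21 (SE 0.69, 95% limits -9.70 to -6.72, edgeR adjusted p = 9.99e-05). In pooled counts, 67 in p57KO against 12137 in p57WT, the wild-type level was 314 times the knockout level (95% counting interval 247 to 406). The genotype labels of all 10 libraries held in this check. Which part of the gene the knockout allele removes was not given in the sources used here, so the remaining counts were not assigned. Without p57KO 1 the log2 fold change was -8.82, and within label number 607 it was -7.28 (edgeR adjusted p = 0.00222).

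**Figure D1:**
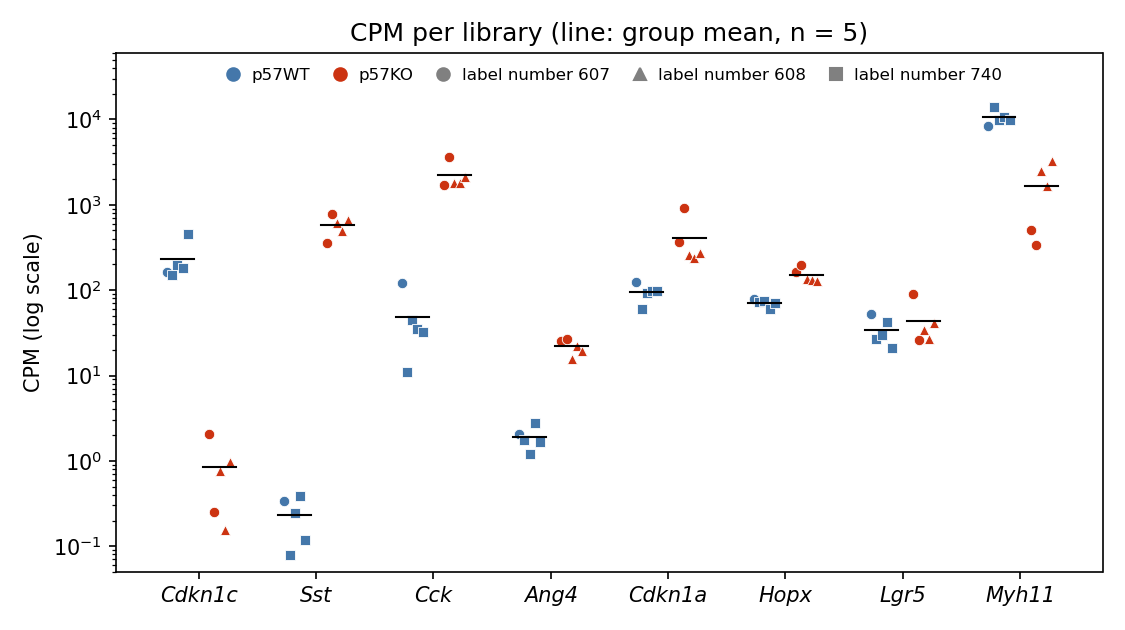
Level of 8 genes in each library in CPM on a log axis, with p57WT in blue, p57KO in red, a symbol for each label number and a line at each group mean (n = 5). Cdkn1c was lower and Sst, Cck, Ang4, Cdkn1a and Hopx were higher in p57KO, with no overlap of the groups (for Hopx the direction turned, to -0.11, on scaling to epithelial markers), Lgr5 overlapped between genotypes, and Myh11 was lower in p57KO.

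The p57KO libraries held more RNA of hormone, absorptive, goblet and Paneth cell genes and of immune and erythroid genes, and less of smooth muscle and fibroblast genes. The largest increase was in Sst, which encodes the hormone somatostatin of enteroendocrine D cells. Other large increases were in genes of neutrophils and other myeloid cells, such as S100a8, Mmp8 and Cxcl2. Large decreases other than Cdkn1c included Vip, a neuropeptide of enteric neurons, and matrix genes such as Hmcn2, Tnxb and Ltbp2. By edgeR, 6107 of 16710 genes passed, 3226 higher and 2881 lower in p57KO, and 4835 of them differed at least 2-fold (2356 higher and 2479 lower). At an unadjusted p below 0.05 there were 7923 genes. The libraries of the 2 genotypes did not overlap for 4042 genes, which is 24.2% of those tested against 0.794% by chance. The authors' deposited table called 7726 genes, 4220 higher and 3506 lower, and 6100 of the 6107 genes were called in both with the same sign.

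The split by direction rested on the scaling. With TMM 52.8% of called genes were higher in p57KO, with DESeq2 53.1% and with limma voom 47.2%. When libraries were scaled to the mean of 18 epithelial markers, the median over all genes moved from 0.08 to -1.10, and 557 genes were higher and 9135 lower (5.75% higher). With the label number as a term, which leaves 2 p57KO libraries against 1 p57WT library within 607, 1009 genes passed (183 higher and 826 lower). With a term for the ribosomal RNA class 2959 passed (1207 higher and 1752 lower), and with the smooth muscle mean as a covariate 2374 passed (1440 higher and 934 lower).

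Sst was at 583 ± 161 CPM in p57KO and 0.235 ± 0.136 CPM in p57WT (log2 fold change 11.42, SE 0.49, edgeR adjusted p = 5.42e-08). In pooled counts, 60666 against 11, the p57KO level was 3179 times the p57WT level (95% counting interval 1777 to 6369). Within label number 607 the log2 fold change was 10.67 (edgeR adjusted p = 0.000447). Gast, which encodes the hormone gastrin and was picked after its values were seen, was likewise higher (log2 fold change 7.45, edgeR adjusted p = 0.000178), with 1121 counts in p57KO and 3 in p57WT (ratio 215, 73.5 to 1046), and was at 6.84 without p57WT 2. Asic5, an ion channel gene, had 1524 counts in p57KO and 2 in p57WT (ratio 439, 121 to 3631). Its log2 fold change was 8.11 over all libraries, 10.69 without p57WT 1, 7.5 without p57KO 3 or p57WT 2, and 4.28 within 607, where it did not pass (edgeR adjusted p = 0.121).

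Other large increases were in genes active in myeloid cells, and their sizes depended on single libraries. The log2 fold change of Mmp8, a neutrophil collagenase gene, was 10.15 over all libraries and 6.20 without p57KO 1 and p57KO 2. For S100a8, which encodes an abundant neutrophil protein, it was 8.62 and 3.19. For Cxcl2, a neutrophil chemokine gene, it was 9.44 and 2.62. The values for Osm, a cytokine gene, were 9.89 and 5.94, for Stfa1, a stefin gene, 9.39 and 4.06, for Srgn, the gene of the granule proteoglycan serglycin, 8.16 and 3.24, for Trem1, a myeloid receptor gene, 8.0 and 4.91, and for Samsn1 7.68 and 4.30. All of these passed in edgeR with and without the pair. Without p57KO 2 alone the values were 7.43 for Mmp8, 5.92 for S100a8, 7.01 for Cxcl2, 7.40 for Osm, 7.93 for Stfa1, 5.91 for Srgn, 5.61 for Trem1 and 5.48 for Samsn1. Without p57WT 5 they were 10.70 for S100a8, 10.04 for Cxcl2, 11.70 for Stfa1, 9.35 for Srgn and 8.77 for Samsn1, and without p57WT 2 they were 8.75 for Stfa1 and 7.09 for Samsn1. Ms4a4c rose by 7.96 (ratio of counts 333, 114 to 1618), and by 5.97 without p57KO 2. Lilrb4a, a leukocyte receptor gene, had 1620 counts in p57KO and 0 in p57WT, with a lower 95% limit of 253 for the ratio, and its log2 fold change was 10.82, or 8.94 without p57KO 2. Under limma voom Cxcl2 (adjusted p = 0.146), Stfa1 (adjusted p = 0.0719) and Srgn (adjusted p = 0.0568) did not pass. With the smooth muscle mean as a covariate the log2 fold changes of Cxcl2, S100a8 and Srgn turned to -1.64, -0.57 and -0.10, none of which passed in edgeR. That covariate could not be separated from genotype.

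Among the large decreases, Hmcn2, which encodes the matrix protein hemicentin, was at 22.9 ± 20.7 CPM in p57KO and 389 ± 74.1 CPM in p57WT (log2 fold change -4.09, SE 0.55, edgeR adjusted p = 0.000394), and at -4.73 without p57KO 5. Tnxb, a tenascin gene, Ltbp2, a latent TGF-beta binding protein gene, and Adam33, a metalloproteinase gene, had log2 fold changes of -3.81, -3.70 and -3.83. Bvht, a long noncoding RNA, and the potassium channel gene Kcnf1 were at -3.84 and -3.76, Scarf2, a scavenger receptor gene, at -3.97 and the sodium-calcium exchanger gene Slc8a2 at -3.96. Without p57KO 5 Scarf2 was at -4.88 and Slc8a2 at -5.17. Vip had 25 counts in p57KO and 782 in p57WT (log2 fold change -6.13, or -7.45 without p57KO 2 and -5.05 without p57WT 3), and within 607 its value was -1.2 and did not pass (edgeR adjusted p = 0.666). Adamts5, a gene for an aggrecan-degrading protease, was at -4.23 over all libraries and at -5.18 without p57KO 2, but without p57WT 5 it was at -2.15 and did not pass (edgeR adjusted p = 0.0576). Ankrd60 was at -4.87 over all libraries and at -8.60 without p57KO 5, and did not pass under limma voom (adjusted p = 0.171).

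Markers of enteroendocrine, absorptive, goblet and Paneth cells were higher in p57KO, while tuft cell genes moved in both directions. Of 23 enteroendocrine genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 3.21. Cck, the cholecystokinin gene, was at 2218 ± 801 CPM in p57KO and 48.8 ± 42.2 CPM in p57WT (log2 fold change 5.51, or 6.18 without p57WT 1). Pcsk1, a prohormone convertase gene, rose by 3.92, Tac1, the precursor of substance P, by 3.21 and Chgb, a chromogranin of secretory granules, by 3.16. The enteroendocrine list passed in camera (adjusted p = 1.29e-13), but not with an estimated correlation (adjusted p = 0.231 with an estimated correlation). Within 607 its median was 2.53 and 5 members passed. With a term for the ribosomal RNA class the median was 3.54 and 21 members passed, and with the smooth muscle covariate it was 2.96 and 15 passed.

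Of 23 absorptive enterocyte genes, 22 rose and 0 fell (the same 22 and 0 adjusted over the list alone), with a median of 2.43. Krt20, a keratin of differentiated villus cells, rose by 4.51, Sis, the sucrase-isomaltase gene, by 4.37 and Slc5a1, the sodium-glucose transporter gene, by 2.54. Camera gave an adjusted p of 1.85e-12, with adjusted p = 0.231 with an estimated correlation. Within 607 the median was 1.2 and 2 members passed. With a term for the ribosomal RNA class it was 2.75 and 22 passed, and with the smooth muscle covariate it was 2.64 and 18 passed.

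Of 16 goblet cell genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 1.5), among them Zg16, a zymogen granule protein gene, at 3.82, Agr2, a mucin-folding disulfide isomerase gene, at 2.58, and Tff3, a trefoil factor gene, at 2.35. Of 9 Paneth cell genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 2.63), among them Ang4, an antimicrobial ribonuclease gene, at 3.55, the defensin gene Defa24 at 2.88, and Mmp7, which encodes the protease that activates defensins, at 2.63. Camera gave adjusted p-values of 1.91e-06 for goblet and 0.000352 for Paneth genes, each with adjusted p = 0.231 with an estimated correlation. Within 607 the medians were 1.03 and 1.39, with 4 goblet and 2 Paneth members passing.

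General epithelial genes were also higher in p57KO. Of 18 epithelial markers, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.19. Examples were Elf3, an epithelial transcription factor gene, at 1.87, Tspan8 at 1.6, the claudin gene Cldn7 at 1.42 and Epcam, an epithelial adhesion molecule gene, at 1.37. Camera gave an adjusted p of 1.79e-06 and adjusted p = 0.378 with an estimated correlation. Within 607 the median was 0.91 and 0 members passed in edgeR. Scaled to these markers, the medians were 2.10 for enteroendocrine, 1.47 for enterocyte, 1.42 for Paneth and 0.32 for goblet genes, against -1.10 over all genes.

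Of 7 tuft cell genes measured, Alox5ap, which encodes a leukotriene synthesis protein also made by myeloid cells, rose by 3.77, and Ptgs1, the cyclooxygenase-1 gene, and Dclk1, a kinase gene, had log2 fold changes of -2.38 and -2.31 (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.319). The list median was -0.67, and it was above 0, up to 0.73, without any 1 of p57KO 3 to 5 or p57WT 1 to 5. With all libraries but no expression filter it was 0.34, so a change in tested members alone could turn it. Without p57KO 1 the median was -0.40 and without p57KO 2 it was -1.69. Alox5ap was at 1.70 without p57KO 2, at 1.07 without p57KO 1 and p57KO 2, where it did not pass (edgeR adjusted p = 0.117), and turned to -0.98 with the smooth muscle covariate. Dclk1 was at -1.56 without p57WT 5, and was at -1.05 within 607 and did not pass (edgeR adjusted p = 0.537).

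Crypt stem cell genes moved in both directions. Lgr5, Ascl2 and Olfm4, markers of cycling crypt base cells picked after their values were seen, had log2 fold changes of 0.35, 0.27 and 0.01 and did not pass (edgeR adjusted p = 0.474, 0.571 and 0.980). Without p57KO 1 the value of Lgr5 turned to -0.09. Scaled to epithelial markers, Olfm4 was at -1.03 and passed, against -1.10 over all genes. Of 20 active stem cell markers, 2 rose and 7 fell (2 and 7 adjusted over the list alone; median -0.06; camera adjusted p = 0.170). Prom1, the CD133 gene, rose by 1.27 and Soat1, a cholesterol esterification enzyme gene, by 1.23, while Nav1, a neuron navigator gene, Rgmb, a BMP co-receptor gene, and Ephb3, an ephrin receptor gene, were at -2.17, -1.97 and -1.92. The list median was -0.66 without p57KO 1 and turned to 0.19 without p57WT 1. Over all libraries this list had camera adjusted p = 0.680 with an estimated correlation. Within 607 its median was -0.70, but p57WT 1 is the only p57WT library there, so that value does not test the list.

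Hopx, whose promoter drove the sorted reporter, was at 151 ± 30.6 CPM in p57KO and 71.3 ± 6.73 CPM in p57WT (log2 fold change 1.08, SE 0.20, edgeR adjusted p = 0.00191), and was at -0.11 when scaled to epithelial markers. It did not pass within 607 (1.21, edgeR adjusted p = 0.0801). Of 10 reserve stem cell markers, Hopx rose and Lrig1, a negative regulator of growth factor receptors, and Igf1r, a growth factor receptor gene, were lower at -1.87 and -2.42 (1 and 2 also adjusted over the list alone; median -0.06; camera adjusted p = 0.769). Of 17 Wnt target genes, 0 rose and 5 fell (the same adjusted over the list alone; median -0.13), among them Dkk3, a dickkopf family gene, at -2.56 and Ccnd1, the cyclin D1 gene, at -1.80. The list missed the threshold (camera adjusted p = 0.0529; adjusted p = 0.396 with an estimated correlation; fry adjusted p = 0.00505). It passed when any 1 of p57KO 1, p57KO 2, p57KO 5, p57WT 2, p57WT 3 or p57WT 4 was left out, with adjusted p-values of 0.0267, 0.0354, 0.0342, 0.0193, 0.0431 and 0.0412. With all libraries but no expression filter it also passed (camera adjusted p = 0.0302).

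Of 13 Notch pathway and lineage choice genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone; median 0.42, turning to -0.68 when scaled to epithelial markers; camera adjusted p = 0.931). Atoh1, the transcription factor gene that commits cells to the secretory lineages, rose by 2.29 (18.7 ± 4.25 against 3.85 ± 1.24 CPM, n = 5 each) and the receptor gene Notch2 was at -2.32. Hes1, a Notch target gene, was at 2.48 (edgeR adjusted p = 0.0471), but p57KO 1 decided this value, with 2424 CPM against at most 305 CPM in the other p57KO libraries. Without p57KO 1 it was 0.39 and did not pass (edgeR adjusted p = 0.509), and without p57KO 1 and p57KO 2 it was -0.30. The call was also lost without p57KO 2 or any 1 of p57WT 1 to 5 (edgeR adjusted p from 0.0551 to 0.0921).

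Genes of mitosis were higher in p57KO, while the direction of DNA replication genes as a list depended on the setting. Of 30 genes of G2/M and mitosis, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.99. Birc5, the survivin gene, rose by 1.70, Cdca3 by 1.61, Ube2c, a ubiquitin-conjugating enzyme gene of the anaphase-promoting complex, by 1.57 and Ccnb2, the cyclin B2 gene, by 1.24. Camera gave an adjusted p of 3.17e-07, with adjusted p = 0.378 with an estimated correlation, and scaled to epithelial markers the median turned to -0.12 with 0 higher and 2 lower, where all genes moved to -1.10 and camera still put the list up (adjusted p = 6.28e-05). Within 607 the median was 0.69 and 0 members passed in edgeR.

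Of 30 genes of G1/S and DNA replication, 1 rose and 2 fell (1 and 0 adjusted over the list alone). Slbp, the histone stem-loop binding protein gene, was at 1.12 and the licensing factor gene Cdt1 and the transcription factor gene E2f1 were at -0.72 and -1.05. The median was 0.09 (turning to -0.99 when scaled to epithelial markers), the camera direction was down and the adjusted p was 0.991. With the smooth muscle covariate the list passed as higher (median 0.78, 10 higher and 0 lower, camera adjusted p = 0.000352). Within 607, where p57WT 1 is the only p57WT library, the median turned to -0.67. Without p57KO 1 and p57KO 2 the median was 0.40 with 11 higher and 1 lower, and the list passed as higher (camera adjusted p = 0.0256). Over all libraries it had adjusted p = 0.997 with an estimated correlation. The numbers higher and lower were 4 and 2 without p57KO 1, 5 and 1 without p57KO 2, 2 and 4 without p57KO 5, 1 and 0 without p57WT 4, and 1 and 1 without any 1 of p57KO 3, p57KO 4, p57WT 1, p57WT 2, p57WT 3 or p57WT 5. The Cdt1 call was lost without p57KO 3 (edgeR adjusted p = 0.0518) or p57WT 4 (edgeR adjusted p = 0.0513). The E2f1 call was lost without any 1 of p57KO 2, p57KO 4 or p57WT 1 to 5 (edgeR adjusted p from 0.0511 to 0.0944), and Slbp was at -0.02 when scaled to epithelial markers.

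Cdkn1a, Cdkn2b and Cdkn3 were higher in p57KO, while the list of cell cycle inhibitors passed in fry but not in camera. Of 9 inhibitors and pocket proteins measured besides Cdkn1c, 3 rose and 0 fell, also adjusted over the list alone (median 0.21, turning to -0.98 with 2 higher and 5 lower when scaled to epithelial markers; camera adjusted p = 0.170; fry adjusted p = 0.000890). Camera also put it up with only high-class ribosomal RNA libraries and with only 607 and 608 libraries (median 0.35 in the latter). These subsets hold p57KO 5 alone and p57WT 1 alone for 1 genotype, so they do not test the list. With an estimated correlation over all libraries camera gave adjusted p = 0.391. Cdkn1a, the p21 gene and a close relative of Cdkn1c, was at 410 ± 287 CPM in p57KO and 94.3 ± 23.1 CPM in p57WT (log2 fold change 2.12, SE 0.39, edgeR adjusted p = 0.00170). Cdkn2b, the p15 gene, rose by 2.31 and Cdkn3, a phosphatase gene that peaks in mitosis, by 1.49. Within 607 Cdkn1a passed at 2.36, and Cdkn2b (1.91, edgeR adjusted p = 0.0650) and Cdkn3 (1.17, edgeR adjusted p = 0.126) did not. Of 17 p53 target genes, 6 rose and 2 fell, also adjusted over the list alone, including the pro-apoptotic gene Pmaip1 at 2.25 and Perp at 1.45. The list median was 0.54, turning to -0.67 with 2 higher and 6 lower when scaled to epithelial markers. Camera gave adjusted p = 0.170, or 0.50 with an estimated correlation, and fry gave adjusted p = 0.0439. Within 607, where p57WT 1 is the only p57WT library, the median was 0.69.

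Smooth muscle and fibroblast genes were lower in p57KO, although the sort selected for the Hopx reporter. Myh11, the smooth muscle myosin heavy chain gene, was at 1642 ± 1244 CPM in p57KO and 10605 ± 2096 CPM in p57WT (log2 fold change -2.69, SE 0.58, edgeR adjusted p = 0.00392). Of 14 smooth muscle and interstitial cell genes, 12 fell and 2 rose, also adjusted over the list alone (median -1.96). The contractile genes Smtn and Lmod1 were at -2.96 and -2.01, and the 2 that rose were Kit (1.32) and Etv1 (1.2), a receptor and a transcription factor of interstitial cells of Cajal. Scaled to epithelial markers Kit and Etv1 were at 0.10 and 0.09 and did not pass. Of 14 fibroblast genes, 12 fell and 0 rose, also adjusted over the list alone (median -2.14), among them the collagen gene Col1a2 at -3.22, the fibrillin gene Fbn1 at -3.07 and Sfrp1, a secreted Wnt inhibitor gene, at -2.51. Camera gave adjusted p-values of 0.000247 for smooth muscle and 2.33e-06 for fibroblast genes, with adjusted p = 0.489 and 0.378 with an estimated correlation.

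The mean log2 level of the smooth muscle list was 7.99 ± 1.03 in p57KO and 9.86 ± 0.28 in p57WT, and that of the fibroblast list was 5.40 ± 1.02 and 7.76 ± 0.59 (SD, n = 5 each; exact permutation p = 0.00794 for each, the smallest possible, and 0.0111 adjusted over 7 scores). The epithelial mean was 8.44 ± 0.25 against 7.31 ± 0.44 and the enteroendocrine mean 7.16 ± 0.41 against 3.72 ± 1.0, with the same exact permutation p. The epithelial, enteroendocrine and muscle levels therefore moved together with genotype, beside the lineage lists. Within 607 the smooth muscle median was -2.89 and 11 members were lower, and the fibroblast median was -2.69 and 6 members were lower.

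**Figure D2:**
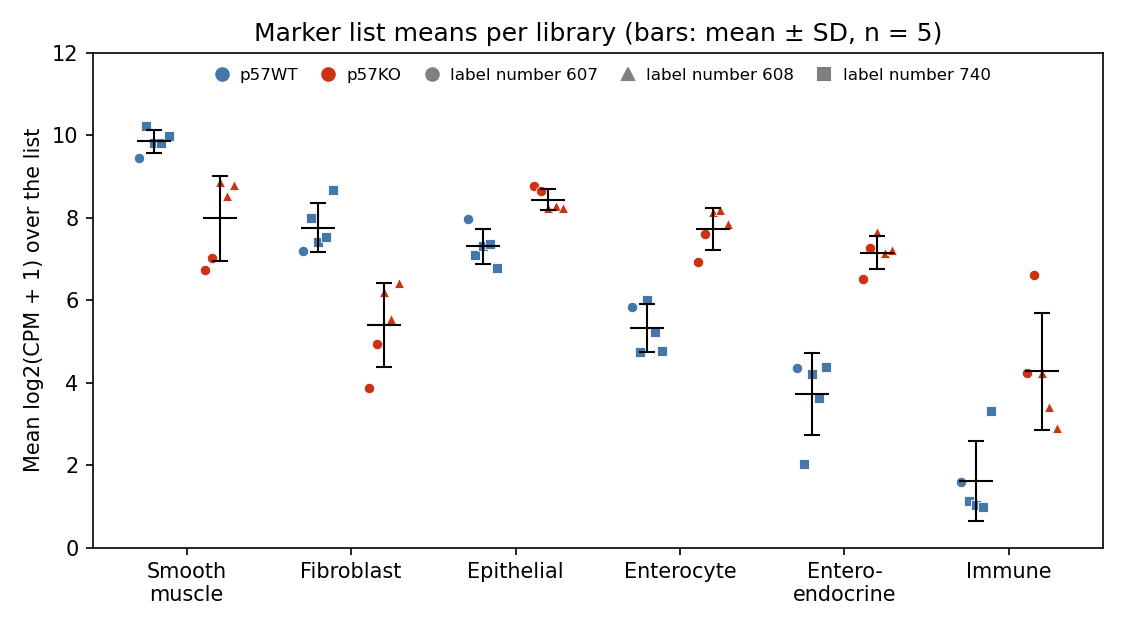
Mean log2(CPM + 1) over 6 marker lists in each library, with p57WT in blue, p57KO in red, a symbol for each label number and bars for the mean ± SD (n = 5). The smooth muscle means of p57KO libraries lay between 6.73 and 8.88 and those of p57WT libraries between 9.46 and 10.23, while the enteroendocrine means lay between 6.52 and 7.65 and between 2.02 and 4.37.

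Immune and erythroid genes were higher in p57KO. Of 14 immune cell genes, 11 rose and 0 fell, also adjusted over the list alone (median 3.48), including Ptprc, the pan-leukocyte antigen CD45, at 4.62 and the lysozyme gene Lyz2 of macrophages and neutrophils at 4.40. Of 12 erythroid genes, 11 rose and 0 fell, also adjusted over the list alone (median 2.99), including the alpha-globin gene Hba-a1 at 4.95. Camera gave adjusted p-values of 7.72e-05 and 2.11e-05, with adjusted p = 0.422 for immune and 0.231 for erythroid genes with an estimated correlation. Without p57KO 2 the members passing fell to 7 in each list, with an immune median of 2.48, and Ptprc, Lyz2 and Hba-a1 were at 3.50, 3.76 and 3.82. Without p57WT 5, with the expression filter run again, the immune median was 5.02 with 14 higher, and these genes were at 5.75, 5.02 and 5.83. Without p57WT 1 the erythroid median was 3.62 with 10 higher. Without p57KO 1 and p57KO 2 there were 10 immune members (median 2.51) and 6 erythroid members. Within 607 the medians were 4.84 and 2.97, with 1 immune and 0 erythroid members passing in edgeR. With the smooth muscle covariate, which could not be separated from genotype, the immune median was 0.80 and the erythroid median 1.5, with 1 member of each passing. With only high-class ribosomal RNA libraries, where p57KO 5 stood alone for its genotype, the medians were 0.95 and 1.87. The mean immune level was 4.28 ± 1.42 in p57KO and 1.61 ± 0.98 in p57WT (exact permutation p = 0.0159).

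Of 13 enteric neuron and glia genes, 1 rose and 5 fell (1 and 7 adjusted over the list alone; median -0.78; camera adjusted p = 0.303). Snap25, a synaptic vesicle fusion gene also used by endocrine cells, rose by 2.58 and Hand2, a transcription factor gene of enteric neurons, was at -2.52, or -3.56 without p57KO 5. With 1 library left out at a time, the number that fell ranged from 1 (without p57KO 4 or p57WT 5) to 6 (without p57WT 1). Of 6 mesothelium genes, 0 rose and 3 fell, also adjusted over the list alone (median -1.35, camera adjusted p = 0.303). The median was -2.17 without p57WT 2 and -2.07 without p57WT 4. With all libraries but no expression filter it was -2.23, so a change in tested members alone could move it this far. Of 6 endothelial genes, 0 passed in edgeR, also adjusted over the list alone, and 1 had an unadjusted p below 0.05 (median 0.66, turning to -0.61 when scaled to epithelial markers; camera adjusted p = 0.387). No mitochondrially encoded gene could be tested.

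Imprinted genes outside the Cdkn1c domain were lower in p57KO. Of 18 measured, 0 rose and 9 fell (0 and 12 adjusted over the list alone), with a median of -1.01. Meg3, a maternally expressed noncoding RNA, was at -2.45 (-1.80 without p57WT 5), Peg12 at -2.78 and Ndn, the paternally expressed necdin gene, at -2.03. Camera gave an adjusted p of 0.00471, with adjusted p = 0.422 with an estimated correlation. Within 607 the median was -0.65. With the smooth muscle covariate the median was -0.22 and the list did not pass (camera adjusted p = 0.440). That covariate could not be separated from genotype, so this loss does not show muscle share as the cause.

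Of 33 neighbours of Cdkn1c on distal chromosome 7, 4 rose and 9 fell (5 and 9 adjusted over the list alone). Th, the tyrosine hydroxylase gene, rose by 4.42 (847 against 15 counts), and Slc22a18, an imprinted transporter gene next to Cdkn1c, rose by 2.05. The phosphatase gene Dusp8 was at -2.29 and Kcnq1ot1, the noncoding RNA of the domain's imprinting centre, was at -1.42, a value that may hold Kcnq1 reads. The median was 0.03 (turning to -1.15 when scaled to epithelial markers), the mean was -0.16, the camera direction was down and the adjusted p was 0.315, while fry passed the list as lower (adjusted p = 0.0160). Without p57KO 5 the numbers were 7 and 10. Within 607, Slc22a18 (1.62, edgeR adjusted p = 0.196), Kcnq1ot1 (-0.98, edgeR adjusted p = 0.414) and Th (4.36, edgeR adjusted p = 0.170) did not pass.

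**Figure D3:**
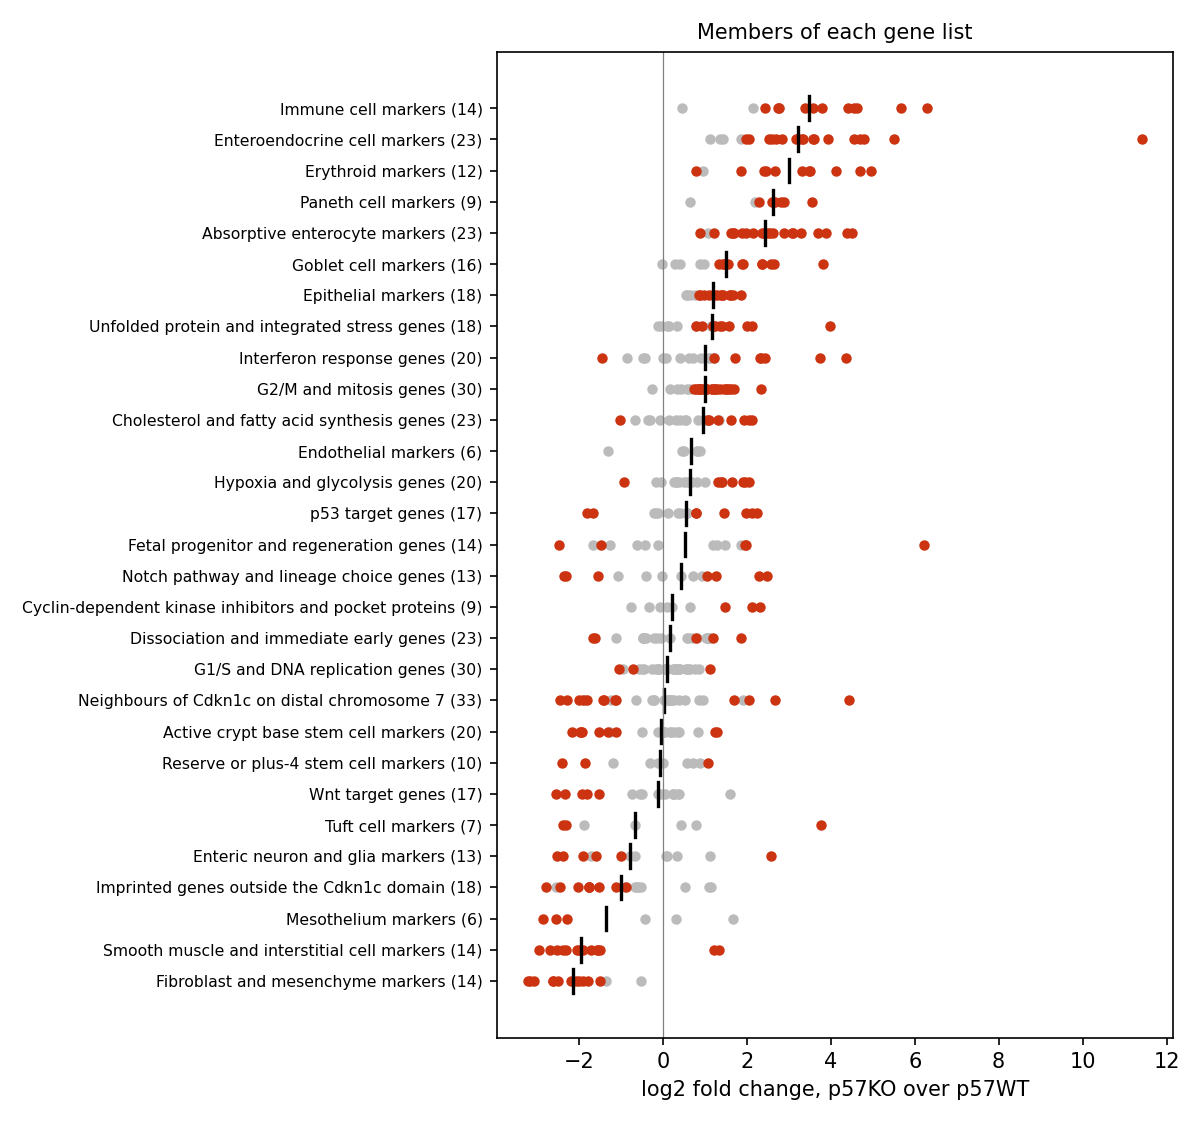
Log2 fold change of p57KO over p57WT for each measured member of 29 gene lists, with called genes (edgeR adjusted p below 0.05) in red, other genes in grey, the median as a black bar and the number of members in parentheses. Over all libraries the highest median was that of immune genes (3.48) and the lowest that of fibroblast genes (-2.14). Without p57KO 2 the immune median was 2.48 and the enteroendocrine median 3.08. When libraries were scaled to epithelial markers, 12 of the 29 medians changed sign, while the median over all genes was -1.10. Among them were G2/M (-0.12), interferon (-0.20) and hypoxia genes (-0.43), which camera still put up.

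Genes of protein folding stress were higher in p57KO. Of 18 genes of the unfolded protein and integrated stress responses, 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.16), among them Sdf2l1 (2.11) and Pdia4 (2.01), which act in folding in the endoplasmic reticulum, and Asns (1.24), the asparagine synthetase gene. Camera gave an adjusted p of 0.000221, with adjusted p = 0.0779 with an estimated correlation. Scaled to epithelial markers the median was 0.01, with 1 higher and 2 lower. Of 20 hypoxia and glycolysis genes, 7 rose and 1 fell, also adjusted over the list alone (median 0.65), including Ndrg1 (1.91) and the glucose transporter gene Slc2a1 (1.65). Camera gave an adjusted p of 0.00689, with adjusted p = 0.50 with an estimated correlation, and the median turned to -0.43 when scaled to epithelial markers, where camera still put the list up (adjusted p = 0.0173). Within 607 the medians were 0.85 for stress and 0.64 for hypoxia genes, with 1 and 0 members passing in edgeR.

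Of 20 interferon response genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.0; camera adjusted p = 0.0683), including Usp18, which removes the interferon-induced modifier ISG15, at 3.74 (4.41 without p57WT 3) and the oligoadenylate synthetase gene Oas1a at 2.42. The median turned to -0.20 when scaled to epithelial markers, where camera put the list up (adjusted p = 0.00162), and to -0.12 with the smooth muscle covariate. The list passed without p57KO 1, p57KO 4, p57KO 5 or p57WT 5 (camera adjusted p = 0.0375, 0.0212, 0.0452 and 0.0493), against adjusted p = 0.671 with an estimated correlation over all libraries. With all libraries but no expression filter it also passed (camera adjusted p = 0.0417).

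Of 23 cholesterol and fatty acid synthesis genes, 7 rose and 1 fell, also adjusted over the list alone (median 0.95, turning to -0.11 with 0 higher and 5 lower when scaled to epithelial markers; camera adjusted p = 0.170). With the smooth muscle covariate the median was 2.40 and 17 members were higher (camera adjusted p = 2.11e-12), while over all libraries, the only setting tested that way, it was adjusted p = 0.805 with an estimated correlation. Fdft1, the squalene synthase gene, was at 2.13 and Srebf2, the sterol regulator gene, at -1.04. Without p57KO 1 and p57KO 2 the median was 1.54 and 17 rose (camera adjusted p = 5.06e-06), and without either alone the list also passed (camera adjusted p = 0.0127 and 0.0312), against adjusted p = 0.805 with an estimated correlation over all libraries. Within 607, where p57WT 1 is the only p57WT library, the median turned to -0.44. With 1 library left out at a time, the number that rose ranged from 3 (without p57WT 5) to 12 (without p57KO 1).

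Of 23 dissociation and immediate early genes, 3 rose and 2 fell, also adjusted over the list alone (median 0.16, turning to -1.19 when scaled to epithelial markers; camera adjusted p = 0.991), and the activity-induced genes Fosb and Nr4a1 were at -1.68 and -1.61. Camera put the list up and fry put it down, and with 1 library left out at a time the number that rose ranged from 2 to 6. Of 14 fetal progenitor and regeneration genes, 3 rose and 2 fell, also adjusted over the list alone (median 0.53, turning to -0.92 when scaled to epithelial markers; camera adjusted p = 0.989), including the keratin gene Krt7 at 1.95 and Ccn2, a YAP target gene, at -2.48. Without p57KO 2 the median was 0.09, and 2 rose and 6 fell.

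The knockout libraries also differed among themselves by label number, among them muscle, sterol, myeloid and stomach genes. Of 14 smooth muscle genes, 11 were higher in the 3 libraries of 608 than in the 2 of 607 and 0 were lower (12 and 0 adjusted over the list alone; median 2.13), with Myh11 higher by 2.68 and Smtn by 2.06. Of 23 cholesterol and fatty acid synthesis genes, 14 were higher and 0 lower (22 and 0 adjusted over the list alone; median 1.84), and of 30 G1/S genes 9 were higher and 0 lower (15 and 0 adjusted over the list alone; median 1.07). The myeloid genes Cxcl2, S100a8 and Stfa1 were lower in 608, at -8.09, -6.71 and -6.45, and so were the stomach mucus genes Tff2, Gkn3 and Muc6, named after their values were seen, at -8.02, -7.47 and -6.95. The summed level of 7 stomach markers was 597 and 232 CPM in p57KO 1 and 2, and 5.39, 8.44 and 8.27 CPM in p57KO 3 to 5. It was 343, 3.20, 790, 485 and 305 CPM in p57WT 1 to 5. Sst, Cdkn1c and Hopx did not pass (0.15, -0.65 and -0.34; edgeR adjusted p = 0.876, 0.694 and 0.509). Of 23 enteroendocrine genes 0 passed in edgeR, also adjusted over the list alone (median 0.39), and of 18 epithelial markers likewise 0 passed (median -0.30).

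By edgeR, 1185 of 20276 genes differed between 608 and 607 in p57KO, 724 higher and 461 lower in 608, and DESeq2 called 2316. With 1 library left out the edgeR number ranged from 445 (without p57KO 3) to 1324 (without p57KO 2). Among p57WT libraries, the 4 of 740 and the 1 of 607 differed in 0 genes by edgeR, with 508 genes at an unadjusted p below 0.05 and 3 genes by DESeq2. In simulated counts for the 20276 genes of that comparison, 1 of 100 planted 4-fold changes was recovered. If as few genes differed in the data as in that simulation, differences of that size would mostly have been missed.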

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

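The tests of smooth muscle share (both), label number, enteroendocrine share, stomach tissue alone and Y-linked genes were chosen after the results were seen, and the tests of ribosomal RNA class, other splits, stomach or pancreas tissue and gut length were chosen before. A library far from the other 4 of its genotype, by Dixon's test at 95%, was found in 45 of 230 groups of values. The test's rate of 1 in 20 holds for independent, normally distributed values. Here CPM values were not log-transformed, nearly all flags were highest values, and many of the genes move together. The number of flags is therefore not read as an excess over chance. Of these, 16 were in p57KO 2, 12 in p57WT 5, 6 in p57KO 5, 4 in p57WT 2, 3 in p57WT 1, 2 in p57KO 1 and 2 in p57WT 3.

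Enteroendocrine and absorptive genes were higher in p57KO libraries, which also held less smooth muscle RNA. A lower share of muscle RNA alone would raise them like epithelial genes. The enteroendocrine mean minus the epithelial mean, however, differed by 2.30 log2 units between genotypes (exact permutation p = 0.00794, all 5 p57KO above all 5 p57WT). This argues against muscle share as the whole cause for enteroendocrine genes. For absorptive genes the difference was 1.28 with overlapping groups (exact permutation p = 0.0159), so they rose more than epithelial genes on average. Their median was 2.64 with the smooth muscle covariate, where 18 members passed, and 2.43 without it. Smooth muscle means did not overlap between genotypes, at most 8.88 in p57KO and at least 9.46 in p57WT. That covariate could therefore not be separated from genotype, so muscle share stays open for absorptive genes. With the ribosomal RNA class as a term the enteroendocrine median was 3.54. That value rests on p57WT 2, the only p57WT library of the low class, and p57KO 5, the only p57KO library of the high class. Their enteroendocrine means were 2.02 and 7.21, each on the side of its genotype, so these libraries argue against the class as the whole cause. Within label number 607 the enteroendocrine median was 2.53 and 5 members passed, against 3.21 and 19 over all libraries, but that comparison and the one of 740 with 607 (-0.60) rest on p57WT 1 alone, so label number stays open. An effect of genotype stays open, through the cell types that the sort caught or through expression within cells, and the measured levels do not separate these.

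Of 100 splits of the 10 libraries into 5 and 5, only the real split gave as many as 6107 genes, and the highest other split gave 1141. A count this high was thus rare among the splits. The real split also followed the first principal component, with 54.2% of the variance. The gene count therefore does not separate genotype from label number. That other split grouped p57KO 1 with p57WT 1, 3, 4 and 5. The next, with 979 genes, was the exact split by ribosomal RNA class. Both kept 4 p57KO libraries together, so their counts do not show a structure apart from genotype. At least as many lists as the real 13 passed in 30 of the 100 splits, with 18 in the highest other split, so chance was not excluded for the list count.

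Sst and Gast were near absent from p57WT libraries. A lower share of enteroendocrine RNA would lower all its genes alike. Ratios among the other members of the enteroendocrine list ran from 2.66 (Insm1) to 58.7 (Cck), against a lower limit of 1777 for Sst. The members thus did not move alike, with or without Sst. Sst was examined because its increase was the largest, and its limit covers counting error only, so its excess decides nothing further. A lower share of D cells alone stays open, and Gast, which was not on the list, was not tested this way. Stomach tissue would bring its own markers, which summed to as little as 0.875% of Sst in a p57KO library and to as much as 790 CPM in a p57WT library, which argues against stomach tissue as the source. The summed stomach markers were below 10% of Sst in 3 of 5 p57KO libraries and 4 of 7 pancreas markers passed as higher in p57KO, although 1 of these, the digestive enzyme gene Ctrb1, was at 2.35, 5.02 and 7.49 CPM in p57KO 3 to 5 and at 4.32 to 7.17 CPM in p57WT, so pancreas tissue stays open and cannot be told apart from a change within the intestine. Another length of gut in p57WT stays open. By edgeR 0 of 13 distal genes were higher in p57WT, but 6 distal and 3 of 8 proximal genes were higher in p57KO. Among these, Nts, Pyy and Gip are also on the enteroendocrine list and Guca2a is on the goblet list. Genes of both regions thus moved the same way, and the test decides nothing.

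Y-linked genes were at a low level in p57WT 4, which had 977 CPM of Xist, the RNA of the inactive X chromosome. The Y-linked gene Eif2s3y was at 104, 110 and 61.0 CPM in p57KO 1, 4 and 5 and at 79.4 CPM in p57WT 3. In the other libraries it was at most 3.92 CPM, the value of p57WT 4. Sex was therefore not balanced between the genotypes, and no term for sex was fitted. Reads from a male p57KO library would have brought 20.8 CPM of Sst, and the upper limit in p57WT 4 was 5.51% of that, which argues against such a source. The levels of Ddx3y, Eif2s3y, Kdm5d and Uty were 6.59%, 4.94%, 9.05% and 4.50% of those in p57WT 3, and the highest over the lowest of these ratios was 2.01. That spread lay within a bound of 2.5 set after the values were seen, so reads or RNA from p57WT 3 or another male p57WT animal could be the source, and no biological explanation was tested.

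In p57KO 2, myeloid genes stood above the other p57KO libraries: Lilrb4a at 54.1 CPM, Mmp8 at 451 CPM, Osm at 499.9 CPM, Cxcl2 at 3548 CPM, S100a8 at 4365 CPM, Srgn at 2018 CPM, Trem1 at 184 CPM, Ms4a4c at 59.8 CPM, Samsn1 at 169 CPM, Alox5ap at 135 CPM and Ptprc at 90.5 CPM. The same library was highest for Cck at 3624 CPM, Cdkn2b at 44.6 CPM, Cdkn1a at 916 CPM, Hba-a1 at 434 CPM and Vip at 0.762 CPM. In p57WT 5, mesenchymal and other genes stood above the other p57WT libraries: Cdkn1c at 458 CPM, Adamts5 at 51.7 CPM, Scarf2 at 67.9 CPM, Meg3 at 651 CPM, Fbn1 at 603 CPM, Col1a2 at 2198 CPM, Dclk1 at 42.6 CPM, Alox5ap at 4.98 CPM, S100a8 at 10.4 CPM, Srgn at 5.69 CPM and Stfa1 at 0.711 CPM, with an immune mean of 3.31.

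In p57KO 5 the highest values were Ankrd60 at 4.61 CPM, Scarf2 at 7.22 CPM, Slc8a2 at 2.70 CPM, Igf1r at 103 CPM, Hand2 at 13.6 CPM and a ribosomal RNA repeat share of 9.47%. In p57WT 2 that share was the lowest of its genotype at 0.0301%, while total counts (25.5 M), Pdia4 (112 CPM) and Fdft1 (46.4 CPM) were the highest. In p57KO 1 the highest values were Hes1 at 2424 CPM and Lgr5 at 90.0 CPM, in p57WT 1 Asic5 at 0.228 CPM, Tac1 at 27.7 CPM and Ascl2 at 18.0 CPM, and in p57WT 3 Vip at 52.5 CPM and Usp18 at 2.42 CPM.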

How the results depend on the processing

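The settings for ribosomal RNA class, epithelial scaling, smooth muscle covariate and the pair p57KO 1 and p57KO 2 were chosen after seeing the data. The smooth muscle covariate could not be separated from genotype, so changes under it do not show muscle share as their cause. Against 6107 genes, 1009 passed with the label number as a term, 0 with only 607 and 608 libraries (1779 at an unadjusted p below 0.05), 2959 with the ribosomal RNA class as a term, 713 with both terms, 0 with only low-class libraries (3730 unadjusted), 1168 with only high-class libraries, 9692 scaled to epithelial markers and 2374 with the smooth muscle covariate. Both counts of 0 come from edgeR with a single p57WT library, and no other tool was run there. The high-class libraries likewise hold a single p57KO library, p57KO 5. With 1 library left out the number of genes ranged from 4763 to 7141. Cdkn1c ranged from -8.82 to -7.80 with 1 library left out, and missed the threshold with only 607 and 608 libraries (-7.77, adjusted p = 0.0576) and with only low-class libraries (-7.75, adjusted p = 0.0929). Against 13 lists, 20 passed with the label number as a term, 0 in camera with an estimated correlation (17 by fry), and 13 to 16 with 1 library left out.

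Directions turned with the smooth muscle covariate for Cxcl2 (-1.64), S100a8 (-0.57), Srgn (-0.10), Alox5ap (-0.98), Hes1 (-2.51, passing as lower, adjusted p = 0.0406) and E2f1 (0.072), and for the medians of interferon (-0.12), fetal (-1.06), immediate early (-0.78), mesothelium (0.26) and reserve stem cell genes (0.10). With label number and ribosomal RNA class as terms they turned for Vip (0.59), Adamts5 (0.30), Dclk1 (0.36), Meg3 (0.23), Kcnq1ot1 (0.10), Fosb (0.62) and the medians of G1/S (-0.89), hypoxia (-0.10) and cholesterol genes (-0.74). With only high-class libraries they turned for Alox5ap (-0.41), fetal (-0.95) and immediate early genes (-0.22), and without p57KO 1 and p57KO 2 for Hes1 (-0.30). Scaled to epithelial markers they turned for Hopx (-0.11), Slbp (-0.019), Olfm4 (-1.03) and the medians of G2/M (-0.12), interferon (-0.20), hypoxia (-0.43), cholesterol (-0.11), p53 target (-0.67), cell cycle inhibitor (-0.98), Notch (-0.68), fetal (-0.92), endothelial (-0.61), G1/S (-0.99), immediate early (-1.19) and chromosome 7 neighbour genes (-1.15), against -1.10 over all genes. In all, the median changed sign for 8 of 29 lists with label number and ribosomal RNA class as terms, 5 with the label number as a term, 5 with only high-class and 6 with only low-class libraries, and 1 to 2 with 1 library left out. With the label number as a term the medians of G1/S and cholesterol genes turned to -0.67 and -0.44, and with only 607 and 740 libraries to -0.66 and -0.45. The cause was not tested. In the counts that follow, a gene was taken to miss the threshold only if it kept its direction. Genes that turned and also lost their call are therefore not in those counts. Of the 105 named genes, 105 kept direction and call with DESeq2 and with DESeq2's size factors in edgeR, 99 with limma voom, 58 missed the threshold with the label number as a term, 23 with the ribosomal RNA class as a term, 62 with both, 47 with the smooth muscle covariate, 21 scaled to epithelial markers, 49 with only high-class, 101 with only low-class, 102 with only 607 and 608 and 7 with only 607 and 740 libraries.

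Between 608 and 607 within p57KO, DESeq2 called 2316 genes against 1185, and leaving out 1 library gave 445 to 1324. Between 740 and 607 within p57WT, DESeq2 called 3 genes against 0 by edgeR. With the title number as a block 5804 genes passed, Cdkn1c was at -8.37 and 15 lists passed. Correlations of deviations between libraries of the same title number were 0.20, 0.05, -0.13, -0.12 and 0.15, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries.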
